A study of Homo sapiens with 2 samples.

How the data were processed

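The series holds 1 input library and 1 immunoprecipitated (IP) library from GM12878, a human lymphoblastoid B cell line transformed with Epstein-Barr virus. N6-methyladenosine (m6A) is a methylated adenosine within messenger and other RNAs. In this assay RNA is broken into fragments, fragments bound by an m6A antibody are recovered, and both these and the unselected fragments (the input) are sequenced. Per the labels' protocols, cells grew in RPMI with 15% serum, total RNA was taken with TRIZOL and column-cleaned, and libraries kept the strand through dUTP. The submitters' processing notes name TopHat 1.1.3 and the genome build hg19. The program that computed coverage and the gene annotation are not given in the sources used here.

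The deposited table lists, per the file headers, 3335372 windows under 47352 gene names, with 5 values each. The coverage values of input and IP are a signal that the authors scaled per library by a factor not given in the sources used here. In both libraries 100.0% of values above 0 were whole multiples of a single step within 0.01 step. The steps and the shape of isolated reads fitted reads of 36 nt in windows of 100 nt placed every 50 nt along exons. A scaled coverage of 1 then equals 5.84 reads per base in the input and 3.71 in the IP. The authors' table also gives, per the file headers, the median coverage over a gene in each library and a window score. Recomputing from the coverage showed that the medians run over all windows listed under a gene name. The score deposited by the authors is a log2 value, the ratio of IP to its gene median over the ratio of input to its gene median, with 1 added to each of the 4 numbers. No recomputed median or score differed from the deposited one by more than 1e-09 (0 cases). The score therefore measures enrichment of a window relative to its own gene, and an enrichment shared by most windows of a gene is divided out.

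From these values the following were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. For each gene name the transcript listing with most windows was kept, with ties settled by order in the table, since listings carry no names of their own. A window was called enriched at a score of 2 or more, which is 4-fold. A region was a run of at least 2 consecutive enriched windows, and its highest window was its peak. The gene-level score was the highest mean of 2 consecutive windows. Genes with a mean scaled input coverage of at least 1 are called measured, a minimum set after the coverage had been seen. The threshold, the run length, the gene-level score, the gene lists and the rule for naming genes were fixed before the data were examined.

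Named were the 12 genes with the highest gene-level score among those with a region of at least 3 windows on a transcript of at least 20 windows, every measured member of the 2 lists of m6A proteins, and from each other list the 2 highest and the 1 lowest measured members. Some genes that this rule names are not reported here. Marker genes named for the input are examples picked from their fixed lists after their values were seen, and other named genes are marked as chosen in that way. Gene names were matched to a RefSeq table of human genes on another genome build, used only for symbols, gene class and gene length. Of the names, 21700 matched a current symbol, 2964 matched through an older one and 22688 were not matched. Of 480 list members, 474 were found, 29 of them under an older symbol. Genes are given under the name used in the deposited table.

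Each group has 1 library, so the difference between IP and input has no replicate check, and no p-value or SD is given. Shares carry exact (Clopper-Pearson) 95% intervals, and gene-level scores carry 95% counting intervals drawn from the read numbers that the steps imply. Both cover counting error only, since PCR copies of a read are not independent and neighbouring windows overlap. Each list's median gene-level score is given as its percentile among 10000 random lists of measured genes of the same size matched on input level, which describes these 2 libraries. Random lists could include members of the list itself, which pulls its percentile toward the middle. Percentiles below 2.5 or above 97.5 are treated as outside the central range.

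The region caller was tested on simulated data made from the coverage of all 47352 genes. Regions were planted only in measured genes with at least 20 windows, 50 at each fold. The caller recovered 16% of those at 4-fold, 76.0% at 8-fold, 92.0% at 16-fold and 96.0% at 32-fold. In addition, 19 genes without a planted region were called. The percentile was tested on 40 simulated lists of 25 genes, with normally distributed scores and no matching of random lists. Of these, 36 lay between 2.5 and 97.5, and after a shift of 1 in the score 33 lay above 97.5. The matching used for the results was therefore not tested.

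Windows carry a gene name, an exon number and a window number. Comparing the listings showed exons in genomic order, so the 2 ends of a transcript could not be told apart by this numbering. Terminal exons were therefore compared as the longer and the shorter terminal exon of a transcript, a choice made after the table had been seen. Distance to the stop codon, untranslated regions, sequence motifs and predicted base pairing need coordinates or sequence of the same build and are not analysed here. Alternatives covered the threshold, run length, transcript choice, depth filter, end windows, background, gene-level measure, matching of random lists, pseudocount, centring on the gene median and the input minimum.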

Results

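m6A was mapped across the transcriptome of GM12878 cells by sequencing fragments recovered with an m6A antibody next to the input fragments. There was 1 library of each kind. On 1 transcript per gene the coverage corresponded to approximately 51.7 M reads of 36 nt in the input and 58.5 M in the IP. The 10 genes with most coverage held 14.6% of it in the input and 8.6% in the IP, and mitochondrially encoded genes held 10% and 6.0%. Input coverage was 0 in 39.9% of windows and IP coverage in 42.1%. Of the 47352 genes, 10756 had a mean scaled input coverage of at least 1 and were treated as measured.

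The input carried the transcripts of B cells. The median input coverage of 30 B cell genes was 11.6, above all 10000 random lists (percentile 100). CD74, the invariant chain of MHC class II, reached 775, MS4A1, which encodes the surface antigen CD20, reached 44.9, and PAX5, the transcription factor that maintains B cell identity, 14.3. A label field names mouse embryonic stem cells as the source while the organism and cell line fields name human GM12878. None of 15 pluripotency genes was measured (0), their median input was 0.00462, and the highest, SOX2, stood at 0.153. Among T cell genes 3 of 15 were measured, TCF7 at 14.4, LCK at 8.28 and CD3E at 1.52, with a list median of 0.0399 (percentile 71.8). Of the other lists, THY1 at 1.69 was the only measured member among 11 fibroblast genes (median 0.00259, percentile 26.8), ITGAM at 1.12 among 10 myeloid genes (median 0.0266, percentile 56.1), and none (0) of 10 erythroid genes was measured (median 0.00540, percentile 31.0). The percentile of the pluripotency list was 30.8 among all genes of the table, and 0.84 among genes above the lower quartile of input.

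The first question was how much of the transcriptome the antibody enriched. Of 1983959 windows, 52318 (2.64%) scored 2 or more, and 2448 scored -2 or less, a ratio of 21.4 to 1. Windows at 2 or more formed 10179 regions in 6642 genes, and among measured genes 4756 of 10756 (44.2%) had a region. At the peak of a region the median scaled coverage was 42.0 in the IP and 2.83 in the input. Regions had a median of 4 windows, and the longest, of 40 windows, lay in RBM12, an RNA-binding protein gene chosen after its value was seen. Most measured genes with a region had 1 (3049 genes), and 615 had 3 or more.

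Counting noise alone was simulated in 5 draws, with a gene's overall IP level kept where both its medians were nonzero. It gave 107 to 138 windows at 2 or more and 20 to 27 genes with a region. At -2 or less it gave 152 to 180 windows against 2448 in the data. The simulation thus falls short of the spread at the low end and may understate the background at the high end. An IP at or below the gene's median was found at 11 peaks (0.108%). With 1 added, such a peak can reach a score of 2 only if its input lies far below the gene's median. In genes of low input this cannot happen, so the small share is partly set by the score itself. Of the 7440 peaks in measured genes, 19.5% had an input below the gene's median and 3.88% an input below 50% of it. The count of genes depends on the threshold, with 11550 at a score of 1 and 3604 at a score of 3, and it falls to 4311 when runs of at least 4 windows are asked for. It also depends on the number added before the logarithm, with 10267 genes when 0.1 is added and 4277 when 5 is added.

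**Figure D1:**
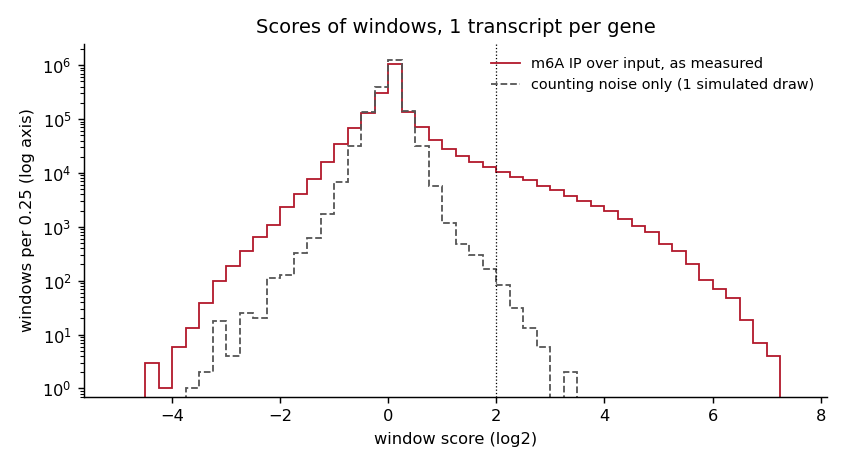
Number of windows (log axis) per 0.25 of window score (log2) in 1 transcript per gene, for the measured m6A IP over input (solid line) and for 1 simulated draw with counting noise only (dashed line). The dotted line marks a score of 2, above which 52318 measured windows lay, against 107 to 138 in the 5 simulated draws. At -2 or less lay 2448 measured windows, against 152 to 180 in these draws.

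Among measured genes, the share with a region differed with transcript length and was lowest among the most abundant transcripts. Measured genes were sorted by number of windows into 4 groups of 2689. A region was found in 11.3% of the group with fewest windows (95% interval 10.2 to 12.6), then in 36.9%, 56.1% and, in the group with most windows, 72.6% (70.9 to 74.3). Sorted by input level in the same way, the share was 48.1% in the lowest group, 53.4% and 46.9% in the middle groups and 28.4% in the highest (26.7 to 30.2). The highest input group also had the shortest transcripts, with a median of 39 windows against 59, 64 and 57 in the other groups, so depth and length are not separated here. Genes below the input minimum had a region in 5.17% of 36501 cases. Protein-coding genes had a region in 49.8% of 8784 cases (48.7 to 50.8), genes classed as long non-coding in 42.0% of 119 (33.0 to 51.4) and pseudogenes in 3.47% of 173 (1.28 to 7.40). No region was found in 175 small nucleolar RNA genes, where 0 cases allow up to 2.09%, nor in 105 microRNA genes (up to 3.45%), but these genes had a median of 2 windows each.

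The position of enriched regions was compared with that of all windows of the same transcripts. The longer terminal exon held 66.4% of the 10179 peaks (65.5 to 67.3) against 50.3% of windows. Internal exons held 23.4% of peaks (22.5 to 24.2) against 38.9% of windows, the shorter terminal exon 5.76% (5.31 to 6.23) against 7.48%, and single-exon transcripts 4.13% (3.75 to 4.53) against 3.16%. Within longer terminal exons of at least 20 windows (5456 exons), enriched windows gathered toward the inner edge, which adjoins the rest of the transcript. With each exon divided into 10 equal parts from that edge, they made up 21% and 21.3% of windows in parts 1 and 2, 13.9% in part 3, 9.02% in part 4 and 2.08% (1.92 to 2.26) in the outermost part. Median input fell along the same parts, from 3.65 in part 1 to 0.879 in the outermost, which lowers scores there. Among windows with an input of at least 5 and at or above the gene median, a check added after seeing the data, the share went from 24.5% and 27.2% in parts 1 and 2 to 5.48% (4.59 to 6.48) in the outermost.

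Internal exons differed by length. In internal exons of up to 5 windows, 193 of 242130 windows were enriched (0.0797%, 0.0689 to 0.0918). The share was 5.29% in exons of 6 to 10 windows, 26.0% (25.3 to 26.7) in exons of 11 to 20 windows from 934 genes, 25.6% in exons of 21 to 40, and 12.1% in longer ones. Median input coverage was 1.47 in internal exons of 1 to 2 windows, where 0.0423% were enriched, 2.77 in those of 3 to 5 (0.0912%) and 3.56 in those of 11 to 20. The longer terminal exon had a higher share than internal exons at 3 to 5 windows (2.14%, 1.54 to 2.91), a like share at 6 to 10 (5.10%), and a lower share in longer exons, with 9.70% at 11 to 20 windows, 9.28% at 21 to 40 and 8.50% beyond. In long internal exons the share was 6.35% (5.54 to 7.24) in the window at the exon edge. It was 33.2% (31.5 to 34.9) in windows starting 250 nt inside. In long terminal exons the share went from 4.66% at the inner edge to 29.3% at 250 nt and 11.2% at 750 nt. Median input was lower at the edge than at 250 nt, with 1.59 against 3.97 in internal and 2.10 against 4.01 in terminal exons. With 1 added to each value, lower input shrinks scores at the edge.

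The exon shares moved with the threshold, from 1.58% against 49.3% at a score of 1 to 0.00867% against 11.5% at a score of 3, with the order kept. Since strand was not used here, the longer terminal exon is not equated with either end of the transcript.

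**Figure D2:**
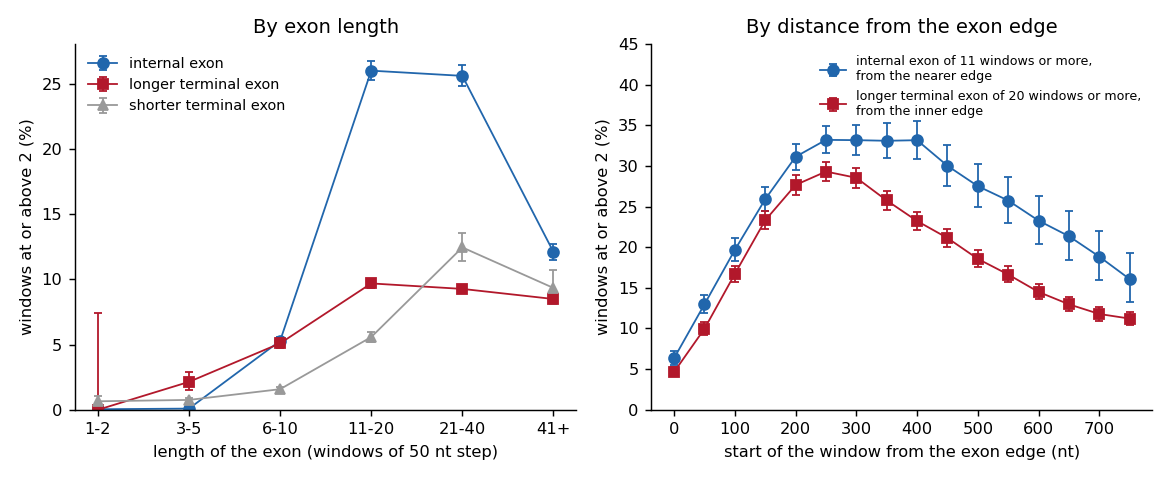
Percent of windows at a score of 2 or more, with exact 95% intervals for counting error as error bars. Left, by exon length in windows of 50 nt step for internal (circles), longer terminal (squares) and shorter terminal (triangles) exons, with 0.0912% in internal exons of 3 to 5 windows and 26.0% in those of 11 to 20. Right, by distance in nt from the exon edge, with 6.35% at the edge of long internal exons and 33.2% at 250 nt.

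The genes with the highest scores held their peaks mainly in a long terminal exon. DDX23, a spliceosomal RNA helicase, had a gene-level score of 6.96 (95% counting interval 6.82 to 7.12), where IP coverage at the peak was 1642 and input 13.1. ARF6, a small GTPase of membrane traffic at the cell surface, also scored 6.96 (6.88 to 7.03), with 6476 against 56.5 in a region of 19 windows. The other 10 genes of this group scored between 6.57 and 6.82. They were SLC5A3, the sodium and myo-inositol cotransporter (6.82), CCNT2, a cyclin of the transcription elongation factor P-TEFb (6.81), FAM210A (6.77), TSPYL1, of the nucleosome assembly protein family (6.73), RSF1, a subunit of a chromatin remodelling complex (6.71), GRIN2A, a subunit of the NMDA glutamate receptor (6.69), PDE7A, a cyclic AMP phosphodiesterase (6.66), IKZF2, the transcription factor Helios (6.64), SLC35E1 (6.62) and GLG1, a Golgi glycoprotein (6.57). Of the 12 peaks, FAM210A's lay in an internal exon, TSPYL1's in a single-exon transcript and the others in the longer terminal exon. Input at the peak was as low as 0.905 in GRIN2A and 1.03 in SLC5A3, whose scores thus rest on fewer input reads. The order among these genes depends on the setting, since ARF6 stood above DDX23 with a pseudocount of 5 (6.83 against 6.57), SLC5A3 with a pseudocount of 0.1 (7.77 against 7.07) and RSF1 without centring (7.09 against 6.86).

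**Figure D3:**
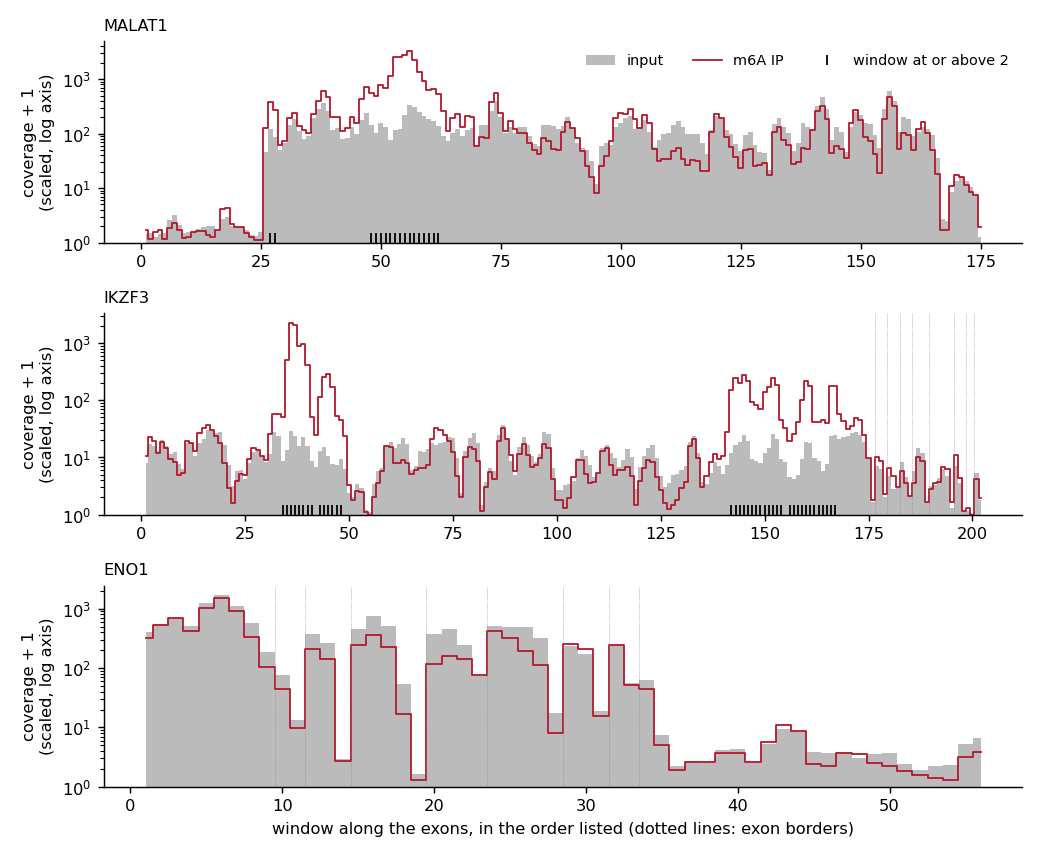
Scaled coverage plus 1 (log axis) of input (grey area) and m6A IP (red line) in each window along the exons in the order listed, with dotted lines at exon borders and ticks under windows at a score of 2 or more. MALAT1 had 17 such windows of 175, IKZF3 39 of 202 and ENO1 0 of 56.

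Most measured transcripts of the methylation machinery itself had a region, but in the main setting neither list's gene-level scores lay outside the central range. All 9 genes of the writer list had a region, with a median gene-level score of 3.32, at percentile 92.7 of random lists and thus inside the central range. RBM15B, an adaptor that recruits the methyltransferase to RNA, scored 4.94 (4.76 to 5.12) with 4 regions, METTL16, a separate m6A methyltransferase, 4.30, ZC3H13 3.71, METTL14, the RNA-binding partner of the catalytic subunit, 3.68, CBLL1 3.32, WTAP, the regulatory subunit, 3.31, RBM15 3.22 and VIRMA (listed as KIAA1429) 2.80. METTL3, the catalytic subunit, was the lowest at 2.61, with 1 region of 3 windows in an internal exon. The order depends on the centring, since RBM15, whose gene-wide log2 ratio of IP to input was 3.03, scored 6.24 without it, above RBM15B at 5.22.

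Of the erasers and readers, 10 of 12 were measured and 7 had a region, with a median of 2.72 (percentile 94.6). YTHDF3, a cytoplasmic reader, scored 5.55 (5.30 to 5.79) in a region of 37 windows in an internal exon, and its relatives YTHDF2 and YTHDF1 scored 3.41 and 2.80. Without centring YTHDF2 scored 5.69, above YTHDF3 at 5.42, and YTHDF1 4.32. The demethylases ALKBH5 and FTO scored 3.0 and 2.51, IGF2BP3 2.96 and YTHDC2 2.65. No region was found in YTHDC1, the nuclear reader (2.24 over its highest pair of windows), HNRNPC (1.24) or HNRNPA2B1 (1.05), while IGF2BP1 and IGF2BP2 fell below the input minimum. Matched on number of windows as well as input level, an alternative chosen after seeing the data, the lists stood at percentiles 80.2 for writers and 62.2 for erasers and readers.

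With centring on the gene median, chromatin regulators and short-lived regulatory transcripts scored highest among the other lists. Without it the zinc finger list (median 4.10) stood above chromatin regulators (4.01) and below the immediate early list (4.54). Of 30 chromatin regulators 26 had a region, with a median score of 4.02 (percentile 100). Their transcripts had a median of 169 windows, and matched on number of windows alone the list stood at 96.99, inside the central range, and matched on window number and input together at 98.94, above it. NSD1, a histone H3 lysine methyltransferase, scored 6.31 with 9 regions and CHD7, a chromatin remodeller, 5.63, while EZH2, the catalytic subunit of Polycomb complex PRC2, had none at 0.90. Of 25 immediate early and short-lived genes 23 had a region, with a median of 3.15 (percentile 99.95). KLF6 and ZFP36L2, a zinc finger transcription factor and an RNA-decay factor, scored 5.38 and 5.27, and ATF3, a stress-induced transcription factor, 0.74 with an input of 2.20 at its peak. MYC at 4.83 and JUN at 4.43, both chosen after their values were seen, lay near the top of this list.

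Genes of the B cell programme and of NF-kB signalling scored high against lists matched on input level alone. Of 27 measured B cell genes 16 had a region, with a median of 2.38 (percentile 99.7). The lymphoid transcription factors IKZF3 and IKZF1 scored 6.29 (6.18 to 6.40) and 6.17 (6.03 to 6.31), and BLNK, an adaptor of the B cell receptor, 0.91. In the NF-kB list 15 of 27 had a region, with a median of 2.55 (percentile 98.3). The list was led by BIRC3, an inhibitor of apoptosis, at 5.32 and ICAM1, an adhesion molecule, at 4.84. Without centring they stood at 4.69 and 4.88, in the opposite order. The chemokine CCL3 had 0.37. With matching on window number added, the percentiles of the B cell and NF-kB lists were 88.4 and 92.8, inside the central range. Zinc finger genes had a region in 12 of 15 measured members, with a median of 3.08 (percentile 96.1). ZNF117 scored 4.85, ZNF100 4.23 and ZNF141 0.96, and their repeated finger domains can share reads between family members.

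Antigen presentation genes lay near the middle. Of 23, 9 had a region, with a median of 1.61 (percentile 71.6). NLRC5, the transactivator of MHC class I genes, scored 4.52 and CALR, an endoplasmic reticulum chaperone, 3.95. Coverage of polymorphic members of this list depends on how well alleles match the reference. Glycolytic and cytoskeletal genes had a region in 3 of 24, with a median of 1.25 (percentile 86.9). These were HK2, a hexokinase, at 5.27, the elongation factor EEF2 at 2.70 and, chosen after its value was seen, ACTB at 2.18, while ENO1, a glycolytic enzyme, had 0.73. Matched on window number alone, this list stood at percentile 1.24, at the opposite side, and matched on window number and input together at 4.03, inside the central range. SR and splicing factors had a region in 5 of 24, with a median of 1.21 (percentile 37.5, and 0.31 with matching on window number and input). U2AF2, the subunit of U2AF that binds the polypyrimidine tract, scored 3.64, SRSF11 3.36 and SRSF9 0.41.

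Transcripts of the respiratory chain, histones, mitochondria and several non-coding host genes scored low. None (0) of 43 nuclear-encoded respiratory chain genes had a region, and their median of 0.79 lay below every random list (percentile 0). The highest were the complex I subunits NDUFA1 at 1.45 and NDUFB8 at 1.43, and the lowest was COX6C, of cytochrome c oxidase, at 0.22. Of 76 ribosomal protein genes 4 had a region, with a median of 0.96 (percentile 68.7, against 0.89 when scores were not centred on the gene median). RPL13 scored 2.97 and RPL29 2.73 (1.12 without centring), and reads of this family can be shared with processed pseudogenes.

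Histone genes had a region in 1 of 21, HIST1H2BD at 2.53, with HIST1H3D at 2.12 and HIST1H4A at 0.09. With the gene median taken over the 1 transcript kept, HIST1H2BD fell to 1.42, below the threshold. The list's median of 0.71 lay at percentile 0.03, and at 71.6 once window number was matched too, since these transcripts had a median of 10 windows. None (0) of 12 mitochondrially encoded mRNAs had a region, with a median of 0.55 (percentile 2.08, against 56.9 without centring), MT-CO2 at 0.70, MT-CO3 at 0.61 and MT-ND4L at 0.06. The list of long non-coding RNAs, which includes several small nucleolar RNA host genes, had a region in 4 of 15. Its median was 0.73 (percentile 0.22, and 3.48 with window number matched). Of all 119 measured genes classed as long non-coding 42.0% had a region, so this list does not stand for the class. MALAT1, an abundant nuclear RNA, scored 4.83 (4.77 to 4.88) and NEAT1, the scaffold of paraspeckles, 2.89, whereas SNHG12, a small nucleolar RNA host gene, had 0.27.

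**Figure D4:**
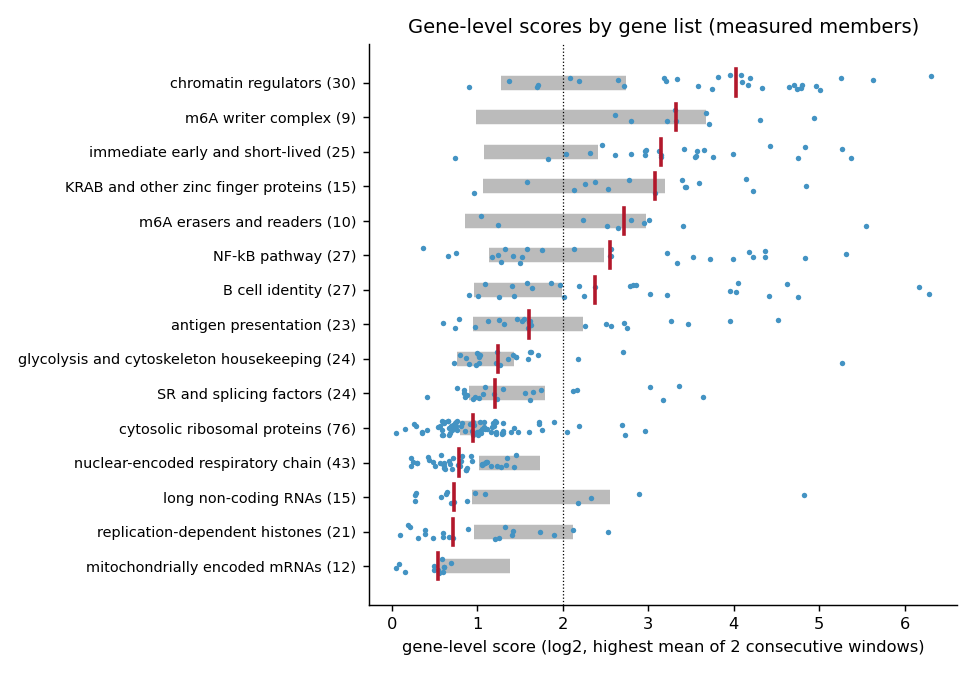
Gene-level scores (log2) of the measured members of 15 gene lists (points, with the number of members in brackets), the list median (red bar) and the central 95% of medians of 10000 random lists matched on input level (grey bar). The dotted line marks a score of 2. Medians ran from 0.55 for mitochondrially encoded mRNAs to 4.02 for chromatin regulators.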

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

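The comparisons by exon number and those with random lists were chosen only after the result was seen, and the test of windows far from regions was set before its result. The window score divides out each gene's median coverage, and those medians hold a signal that the comparisons above do not use. The median log2 ratio of gene-median IP to gene-median input (both plus 1) was -0.13 over all measured genes. It was 0.79 for the immediate early and short-lived list, 0.75 for the zinc finger list, 0.35 for the m6A writers, 0.044 for the NF-kB list and 0.027 for the B cell list. Each of these 5 lay above the central range of random lists matched on input level and window number, at percentiles 100, 100, 97.9, 97.8 and 98.6.

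Some transcripts were thus recovered along most of their length while showing no region. Of 159 measured genes with a gene-wide ratio of at least 4-fold, 81 had no region. Over all measured genes 44.2% had a region, so the lack of one is not particular to these genes. GPR183, a chemotactic receptor of B cells, had a median IP of 189.9 against an input of 14.3, a log2 ratio of 3.64, and a gene-level score of 1.73 that rises to 5.37 without centring. EVI2B had 113 against 14.6 (ratio 2.87), SDHAF1, an assembly factor of succinate dehydrogenase, 47.2 against 2.76 (3.68), and SERTAD1 27.8 against 1.86 (3.33). These were chosen after their values were seen, and each has 1 or 2 exons. Genes with 1 or 2 exons made up 59.1% of the 159 and 16.3% of all measured genes, but these kinds differed. The 661 genes with 2 exons had a median ratio of 0.49, with 9.68% at 4-fold or more, and the 1087 single-exon genes -0.34 with 2.76%, below the -0.23 of genes with 11 or more exons. Of the single-exon genes, 865 lay in the group with fewest windows (median ratio -0.53), and the next groups by window number stood at 0.40, 0.50 and 0.04.

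Genes of like input level and window number did not have such ratios in general in these 2 libraries. Medians of random lists matched on both had a central range of -0.35 to 0.086 for the immediate early list. For the zinc finger list the range was -0.26 to 0.19. The lists stood at 0.79 and 0.75, at percentile 100 each, but the same comparison had picked them out, and there was 1 library of each kind. Spread from strong regions into the rest of the gene remains open for both lists. In windows far from any score of 1 or more, the median log2 ratio was 0.14 (95% interval -0.13 to 0.33) for the former and 0.15 (-0.13 to 0.28) for the latter, against -0.18 over all measured genes. A candidate explanation is that transcripts with few exons are methylated along most of their length, and the tests left it undecided. Among genes of like window number, those with 1 or 2 exons were compared with those with 6 or more. They exceeded the latter by 0.87 and 0.85 in the middle of 4 groups by window number. The difference was 0.38 (0.19 to 0.66) in the group of longest transcripts and -0.05 in that of the shortest. The shortest group pools unlike kinds. Its 348 genes with 2 exons had a median ratio of 0.35 and its 865 single-exon genes -0.53, against -0.23 for 6 or more exons. Gene class was not matched in this comparison.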

How the results depend on the processing

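The alternatives of pseudocount, centring, transcript medians, joint matching and input minimum were chosen after seeing the data; the others were planned. Each score sets the IP against the 1 input, and with 1 library per group no pairing over replicates was possible. Stop-codon distance, motif and pairing alternatives were not run. Over the main results and their alternatives, 131 values stayed below, inside or above the central range as before (some inside it crossed its middle) or within the limit set for counts and shares, 27 moved, 16 became weaker, 12 stronger and 12 changed side. Where the alternative's own construction does not show it, the cause was not tested.

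Of 52318 windows and 6642 genes, a threshold of 1 gave 128880 and 11550, a threshold of 3 gave 20456 and 3604, a pseudocount of 0.1 gave 89499 and 10267, and a pseudocount of 5 gave 27534 and 4277. Runs of at least 4 windows left 4311 genes. These follow from looser or stricter calling. All transcripts together held 94932 windows, since further listings of the same genes are counted. Without centring there were 71172 windows and 7143 genes, which the limit set for counts left among the values that stayed. The excess of peaks in the longer terminal exon, 16.1 percentage points, was 11.9 and 17.2 at thresholds of 1 and 3, 15.1 with single windows, 17.8 over all enriched windows, 17.8 against all transcripts, 13.8 and 18.2 with pseudocounts of 0.1 and 5, and 15.1 without centring.

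The share of enriched windows in internal exons of up to 5 windows, 0.0797%, became 1.58% and 0.00867% at thresholds of 1 and 3, and 0.397% and 0.0219% with pseudocounts of 0.1 and 5. In exons of 11 to 20 windows, 26.0% became 49.3%, 11.5%, 31.8% and 15.8% in the same order, and 29.1% without centring. Long exons stayed above short ones in each of these.

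List percentiles depended on what random lists were matched for and on the gene-level measure. Without matching they were 88.3 for B cell genes, 93.7 for NF-kB, 97.52 for zinc fingers and 0 for ribosomal proteins, the last on the opposite side. With matching on window number they were 65.7 for B cell genes, 88.1 for NF-kB, 96.99 for chromatin regulators, 0.17 for SR factors and 3.71 for mitochondrial mRNAs, and on the opposite side 1.24 for housekeeping genes and 55.1 for histones. With matching on both they were 88.4 for B cell genes, 92.8 for NF-kB, 0.31 for SR factors, 3.48 for long non-coding RNAs, 98.94 for chromatin regulators, 4.03 for housekeeping genes and, on the opposite side, 71.6 for histones. A pseudocount of 0.1 gave 96.1 for NF-kB, 97.53 for erasers and readers and 2.96 for mitochondrial mRNAs, and a pseudocount of 5 gave 95.4 for NF-kB, 97.6 for zinc fingers, 98.2 for writers and 4.08 for mitochondrial mRNAs. Genes with an input of at least 0.2 put zinc fingers at 99.7.

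Without centring, zinc fingers stood at 99.8, ribosomal proteins at 0.89 and mitochondrial mRNAs at 56.9, the last 2 on the opposite side, and MT-ND4L changed sign to -0.31. The median score over all windows lies near 0 by construction, because scores are centred on the gene median, and says little about regions. It put B cell genes at 4.70, NF-kB at 10.3, zinc fingers at 0.10, immediate early genes at 0.09, long non-coding RNAs at 64.7 and respiratory genes at 76.7, all on the opposite side, and chromatin regulators at 71.7, mitochondrial mRNAs at 16.8, histones at 33.4 and ribosomal proteins at 99.9. Among genes above the lower quartile of input, pluripotency, fibroblast and erythroid markers stood at 0.84, 0.37 and 0.28. Scores of the 70 named genes moved by more than their counting interval in 19 genes with the highest single window, 28 and 47 with pseudocounts of 0.1 and 5, 5 with medians of 1 transcript, and 44 without centring besides MT-ND4L.

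Calling limits the low end. Regions planted at 4-fold, the threshold itself, in measured genes of at least 20 windows were recovered in 16% of 50 cases. Genes without a region are therefore not shown to lack m6A. Genes below the input minimum had a region in 5.17% of cases against 44.2% of measured genes, and depth was not varied in the simulation. Short transcripts leave few windows in which one could be seen (11.3% had a region in the group with fewest windows, percentile 71.6 for histones once windows are matched).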

Other observations

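The tests of edge windows, of whole genes and of gene medians below were chosen only after the result was seen, as were the gene families, which were grouped by name. Among measured genes, 148 of 196 with ZNF names had a region (75.5%, 68.9 to 81.4, against 43.6% of other genes), and their median gene-wide log2 ratio of IP to input was 0.72. KLHL and KBTBD genes, adaptors of cullin ubiquitin ligases, had a region in 16 of 18 (88.9%, 65.3 to 98.6), histone lysine demethylase and methyltransferase genes (KDM and KMT names) in 21 of 26 (80.8%), ubiquitin-specific proteases in 24 of 35 (68.6%) and solute carriers in 88 of 135 (65.2%).

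Other families had a region less often. Genes with PSM names, of the proteasome, had a region in 5 of 38 (13.2%, 4.41 to 28.1). Genes with NDUF names had one in 3 of 43 (6.98%), a set other than the respiratory chain list above. Histones (HIST names) had a region in 3 of 66 (4.55%) and small nucleolar RNA host genes (SNHG names) in 0 of 12, which allows up to 26.5%. Mitochondrial ribosomal proteins, with a median of 28 windows, had a region in 21 of 77 (27.3%, 17.7 to 38.6), against 4 of 76 (5.26%, 1.46 to 12.9) for cytosolic ones with 18 windows. Transcript length differs between these families and was not matched here.

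Enriched windows were nearly absent from short internal exons. Low coverage near splice junctions is excluded as the whole cause, since among well-covered windows 30.2% (29.0 to 31.5) were enriched in internal exons of 11 to 20 windows and 0.131% (0.104 to 0.163) in exons of up to 5. Enrichment of whole genes is excluded too: over all 1287 measured genes with internal exons of up to 5 and of 11 or more windows, enriched or not, IP was at least 4-fold above input, without centring on the gene median, in 0.118% (0.0893 to 0.152) of 49346 windows of short internal exons, against 0.0737% in short internal exons of other measured genes. A general penalty at exon edges falls short, with 6.35% (5.54 to 7.24) at the edges of long internal exons against 0.0797% in all windows of short ones. A hypothesis is that adenosines near splice junctions are largely kept from methylation and those some 250 nt inside long exons are not. Lower input at exon edges also lowers scores there, and the profile by distance was not repeated in well-covered windows. Fragment length, base composition and motif density were not tested and may contribute.

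Low scores of abundant short transcripts have different standing by list. For histones, few windows per transcript may be enough, since the percentile rose from 0.03 with matching on input to 71.6 with window number added. Ribosomal proteins stood at percentile 0 without matching, 68.7 matched on input alone and 55.6 with window number added. Their few windows therefore cannot be told apart from their high input, and the random lists could hold members of the list itself. For respiratory chain genes few windows are not enough, at percentile 0.61. Enrichment along the whole transcript, hidden by centring, is argued against for ribosomal proteins (median log2 gene-wide ratio -0.55, 95% interval -0.66 to -0.48) and respiratory genes (-0.39, -0.54 to -0.24), both below the -0.13 of all measured genes, while histones at -0.30 (-0.43 to -0.09) leave it open. Low methylation of respiratory chain transcripts is thus a hypothesis that both tests left standing, and no biological explanation was tested by the design. Random lists were not matched on exon length, and short internal exons were rarely enriched, so the part of exon structure in this list was not tested.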
